A study of Drosophila melanogaster with 6 samples.

How the data were processed

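Total RNA from DGRC S2 cells was labelled and hybridised to 6 Affymetrix Drosophila Genome 2.0 arrays, 1 sample per array, as 2 untreated, 2 mock and 2 NELF-depleted samples. Groups and replicate numbers come from the sample titles. The deposited table holds 1 linear intensity per probe set and array for 18952 probe sets, all above 0 and up to 19041.7. The authors' series design text says that scans were read with GeneChip Operating Software 1.2.0.037 or Affymetrix Command Console 1.1 and imported into Rosetta Resolver 6.0. Which array used which scanning software, how probes were summarised into the deposited intensities, how arrays were scaled and whether background was subtracted are not given in the sources used here. Array medians on the log2 scale differed by 0.255, so the deposited values are not at a common level between arrays.

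From the deposited intensities, log2(value + 0.819) was taken, the offset being the 5th percentile of all values, which understates changes of dim genes. Because the array medians differed by more than 0.1, the 6 arrays were quantile normalized over all 18952 probe sets; the 183 control probe sets were then left out. In the probe annotation 13647 probe sets had exactly 1 gene, 402 had several and 4720 others were not listed; probe sets without exactly 1 gene were left out of gene tests. The probe set with the highest mean over all arrays stood for its gene, giving 11981 genes; 1 symbol given to 2 genes was left out. Symbols were updated through gene identifiers for 11893 genes with the RefSeq gene table of Release 6 plus ISO1 MT, which was used only for names, for the order of genes and for which neighbouring genes overlap. The deposited table names no genome build, so no position is given. A list member was taken by an older name only if that name is not the current symbol of another gene, a rule added after a few wrong matches were found once list results had been seen; the lists called were the same before and after. A comparison of gene lengths was also run, and is left out because no genome build is named.

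Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit with 3 group means over all 6 arrays, 3 residual degrees of freedom, eBayes, Benjamini-Hochberg adjustment, called at an adjusted p under 0.05), two-sided. No block was used, since the labels do not say what the replicate numbers mark. The single-prior test had 1.2 prior degrees of freedom and the alternative with an intensity-dependent prior had 7.31. Standard errors are those of the intensity-dependent fit, since changes are the same in both. On 5 simulated data sets of 11981 genes, 200 genes were changed in NELF-depleted against mock, all with control means above the background level given below. The single-prior test recovered 0%, 0.299% and 57% of 1.5, 2 and 4-fold changes, with 6.9% false calls. The intensity-dependent test recovered 21.5%, 54.6% and 86.4%, with 3.74% false calls. Each gene's residual SD, with 3 degrees of freedom, served as its true SD, which overstates how much genes differ in spread. The rates hold for that setting only and do not settle which test is better on the real arrays. The scripts were thus checked on simulated data with known answers.

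Background was set at the 95th percentile of 17 tag control probe sets, a normalized log2 level of 3.88 or a deposited intensity of 14.6; 6532 genes had a mean above it. A gene whose lower group mean is below it is given as "at least N-fold", the brighter group's mean against the background level. The median absolute difference between the 2 arrays of a group was 0.14, 0.165 and 0.141 for untreated, mock and NELF-depleted above background and 0.787, 0.863 and 0.844 below it. The 2 arrays of each group had 0 probe sets with exactly equal deposited values.

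Named genes follow a rule fixed before the data were examined: all measured NELF subunits; in NELF-depleted against mock the 14 genes up and 14 down with the largest change among called genes whose arrays do not overlap between groups and whose higher mean is above the median gene; in other comparisons 5 up and 5 down; up to 4 members of each list by smallest p; and, without calls, the 5 genes of smallest p. Since the single-prior test called none, the rule was also applied to the intensity-dependent test, a decision made after seeing this. Lists needed 3 or more measured genes and were tested with camera (preset correlation 0.01, and estimated correlation beside it) on the same values, adjusted over 24 lists. Limma's fry test, also fixed beforehand, was run beside camera. It asks whether a list shifts in a common direction, not whether it shifts more than other genes. The list of lysosomal genes and the families by symbol in the closing section were chosen after the calls were seen.

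Alternatives were other scalings (as deposited, array medians, hybridization controls), offsets (1st and 25th percentile, 50 intensity units), filters on dim genes (40th percentile, median), the median over probe sets, prior settings, the replicate number as a block, thresholds, all probe sets, only the groups compared and leaving out each array. For shared arrays, 100 sets of unchanged groups were simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.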

Results

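Messenger RNA levels were measured in Drosophila DGRC S2 cells, an embryo-derived line with features of macrophage-like blood cells, on Affymetrix Drosophila Genome 2.0 arrays. One group was left untreated, a mock group received dsRNA against bacterial β-galactosidase, and the remaining group was depleted of NELF with dsRNA against the subunits NELF-B and NELF-E. Both dsRNA treatments lasted 96 hours, and each group had 2 arrays, 6 in all. NELF, the negative elongation factor, holds RNA polymerase II in a paused state shortly after it starts transcription. The comparison of NELF-depleted with mock cells asks which mRNAs differ after 96 hours of dsRNA against NELF subunits, with untreated cells as a second control. These arrays measure neither NELF protein nor pausing. The median deposited intensity was 13.9 and 14.2 on the untreated arrays, 14.1 and 12.1 on the mock arrays and 11.96 and 11.77 on the NELF-depleted arrays. After quantile normalization, which itself makes such counts alike, from 6948 to 7012 genes per array lay above background. The number of arrays limits the precision of every value. Nothing in the labels says whether arrays of a group came from separate cultures, so p-values measure only the spread between these arrays.

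The mRNAs of both targeted subunits fell. Normalized log2 levels of NELF-B (gene identifier 31681) were 8.05 ± 0.0728 (SD, n = 2) in untreated, 7.99 ± 0.0756 in mock and 6.05 ± 0.273 in NELF-depleted cells. For Nelf-E (gene identifier 38982) they were 8.27 ± 0.170, 8.22 ± 0.0789 and 5.82 ± 0.115. Against mock, 26.1% of the NELF-B mRNA and 19.0% of the Nelf-E mRNA remained, log2 fold changes of -1.94 (SE 0.170) and -2.40 (SE 0.155). TH1, which encodes the NELF-D subunit and was not targeted, had a log2 change of 0.40 (SE 0.127) that did not pass the test over all genes (adjusted p = 0.244), and Nelf-A was not measured by a probe set of its own. Both targets were lower on each NELF-depleted array than on all 4 control arrays. Limma with an intensity-dependent prior gave adjusted p-values of 0.000284 for NELF-B and 7.37e-05 for Nelf-E, whereas limma with a single prior variance for all genes gave 0.139 for both.

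**Figure D1:**
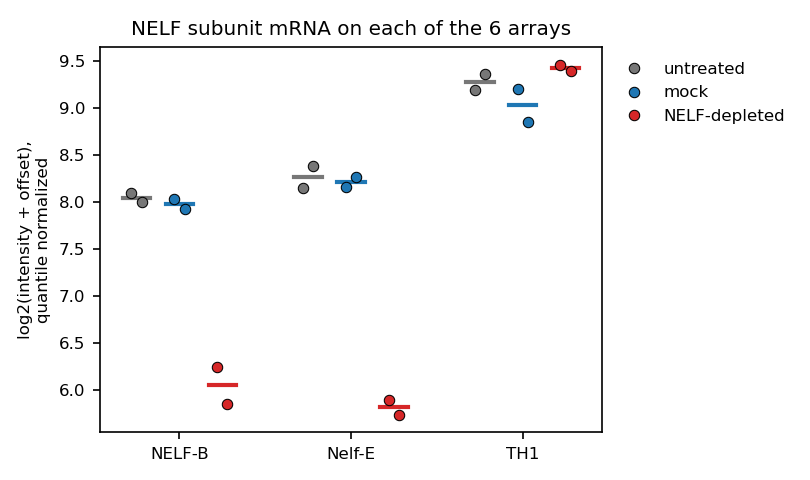
Normalized log2 intensity (vertical axis) of NELF-B, Nelf-E and TH1 on each of the 6 arrays, by group (colour); points are arrays and lines are group means of 2 arrays. The NELF-depleted means of 6.05 for NELF-B and 5.82 for Nelf-E lie below all control arrays, while TH1 lies at 9.43 in NELF-depleted and 9.03 in mock cells.

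By limma with an intensity-dependent prior, many more mRNAs were called lower than higher in NELF-depleted than in mock cells. Among the largest falls were those of QC (glutaminyl cyclase), the membrane-contact protein gene Esyt2, the mitochondrial carrier gene Sfxn1-3 and Sgsh, which encodes a lysosomal sulfatase that degrades heparan sulfate; their log2 fold changes lay between -2.45 and -2.0. The largest rises were in bbg, which encodes a PDZ-domain scaffold, at 2.41 (SE 0.395), CG9008 at 1.80 (SE 0.291) and the inositol hexakisphosphate kinase gene Ip6k at 1.35 (SE 0.162). In all, 162 of 11981 genes changed, 130 lower and 32 higher, with 2 arrays per group.

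These 162 calls depend on the prior variance used. The test fixed before the data were examined, limma with a single prior variance, called 0 genes after Benjamini-Hochberg adjustment (smallest adjusted p = 0.139), although 1097 genes had an unadjusted p under 0.05 where 599.1 were due by chance. Limma with the intensity-dependent prior had been fixed beforehand as an alternative and found 1320 such genes. The share of falls was smaller at this unadjusted threshold, with 740 lower and 580 higher. By the single-prior test 649 were lower and 448 higher. Limiting the single-prior test to genes above the median level, also fixed beforehand, called 175 genes, 138 of them lower. Taking the intensity-dependent prior to describe genes was decided after the single-prior test had called none, and "rose" and "fell" below refer to it. By the single-prior test the 5 genes of smallest p, none past the threshold (adjusted p = 0.139 each), were QC, Sgsh, Nelf-E, Esyt2 and PGRP-SB2, the last at least 1.44-fold higher than a mock level below background.

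Of the genes that fell, QC had a log2 fold change of -2.45 (SE 0.0948, adjusted p = 1.22e-06) and Sgsh one of -2.0 (SE 0.1, adjusted p = 8.48e-06). Esyt2 fell by 2.12 (SE 0.178) and CG34417 by 1.82 (SE 0.15), with adjusted p-values of 0.000258 and 0.000253. CG34232 and Sfxn1-3 both changed by -2.08 (SE 0.187 and 0.264). Pgant2, a glycosyltransferase gene that starts mucin-type O-glycans, fell by 2.04 (SE 0.260), LManII, a lysosomal α-mannosidase gene, by 1.84 (SE 0.308) and path, an amino acid transporter gene, by 1.80 (SE 0.263). CG32813 changed by -1.95 (SE 0.296) and CG15695 by -1.86 (SE 0.374). Another 3 genes dropped below the background level, so that only a bound can be given. The neprilysin-like gene Nepl21 was at least 4.56-fold lower, the serpin gene Spn77Ba at least 2.90-fold lower and CG4250 at least 3.54-fold lower, with adjusted p-values of 0.0202, 0.0377 and 0.0459.

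Among the genes that rose, bbg (adjusted p = 0.0133), CG9008 (0.0121), Ip6k (0.00203) and CG34328 had the largest changes, the last at 1.34 (SE 0.253). AMPdeam, which encodes AMP deaminase of purine metabolism, rose by 1.13 (SE 0.132), oaf by 1.09 (SE 0.208) and CG2247 by 1.09 (SE 0.123). Smaller rises were seen in the glycogen-targeting phosphatase subunit gene Gbs-70E (0.86), ckd (0.83), the Arf GTPase-activating protein gene Asap (0.80), CG3376 (0.78), the mitochondrial ADP/ATP carrier gene Ant2 (0.77) and the serpin gene Spn88Ea (0.72), with SEs from 0.092 for Spn88Ea to 0.164 for ckd. The median absolute log2 fold change of the 162 genes was 1.00, and 81 changed at least 2-fold by their fitted values, 74 of them lower and 7 higher. Of these 28 genes, 8 (CG9008, AMPdeam, oaf, Ant2, Spn88Ea, Sfxn1-3, Spn77Ba and CG32813) were read by probe sets with the suffix _s_at and 7 (Ip6k, Gbs-70E, CG3376, Esyt2, LManII, CG34417 and path) by ones with the suffix _a_at, which mark probes matching several transcripts, of different genes or of the same gene.

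**Figure D2:**
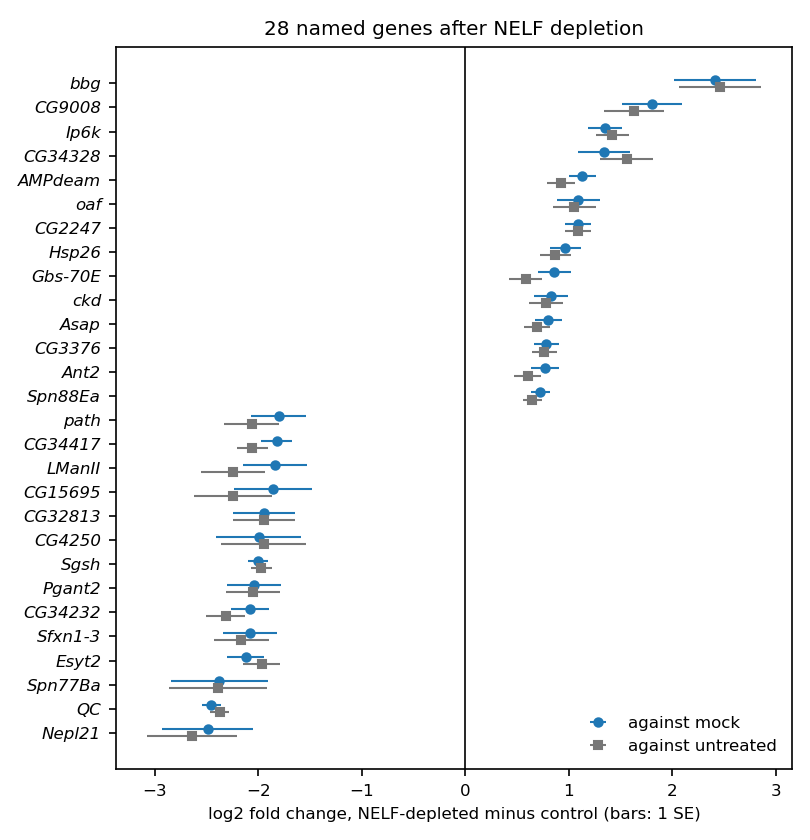
Log2 fold change (horizontal axis) of the 28 named genes (vertical axis) in NELF-depleted cells against mock (circles) and against untreated cells (squares); bars are 1 SE from limma with 2 arrays per group. All 28 genes have the same direction against both controls; the fitted values of Nepl21, Spn77Ba and CG4250 are not bounds, since their level after depletion was below background.

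With each array centred on its median instead of quantile normalized, 54 genes were called, 48 lower and 6 higher. With the intensities as deposited, 54 were called, 53 lower and 1 higher, and with arrays scaled on the spiked-in hybridization controls, 2726 were called, 2709 lower and 17 higher; these scalings shifted the median of all genes by -0.0674 and -0.422. Values for which no scaling is named are from the quantile normalized arrays. Leaving out mock replicate 1 or 2 left 79 or 74 calls, and leaving out NELF-depleted replicate 1 or 2 left 92 or 68. NELF-B, Nelf-E, Ip6k, QC, Esyt2, CG34232, Sgsh and CG34417 were the 8 of 30 genes (both targets and the 28 named) that stayed called in all 15 other settings of this test. Among other rises, bbg stayed called in 9 of these settings, CG9008 in 10, AMPdeam in 13, CG2247 in 14, oaf in 8, and Asap and Ant2 in 7 each. Bbg lost the call as deposited, with the median over probe sets, and without any single mock or NELF-depleted array. The median over probe sets also ended its call against untreated cells and against both controls. CG34328, Gbs-70E, CG4250, CG15695, Spn77Ba and ckd, called in 6, 5, 5, 5, 4 and 3 of them, lost the call when any single array was left out.

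Of 24 gene lists fixed beforehand, 3 were called in NELF-depleted against mock cells by limma's camera test with a preset correlation, all lower. With an estimated correlation none was (adjusted p = 0.714 for each of the 3). Limma's fry test called only the NELF subunits (adjusted p = 0.0224). It did not call glycolysis (0.12) or immune effectors (0.152). Its mixed form, which counts changes in either direction, passed for both (fry adjusted p = 0.0159 and 0.0265). That form also passed for lists that camera did not call, such as Toll and Imd components (0.000264), but not for others, such as proteasome genes (0.54). The glycolysis list, the enzymes and transporters that take up and split glucose, had 11 measured members, all 11 with lower values (median log2 change -0.33, camera adjusted p = 0.00121). No single member passed over all genes, and 7 passed adjusted over the list alone. Among them were Tpi (-0.56, SE 0.131), Pfk (-0.72, SE 0.190), Gapdh1 (-0.32, SE 0.0887) and the sugar transporter gene Tret1-1 (-0.88, SE 0.216). Under the scalings by deposited values, array medians and hybridization controls the list median was -0.39, -0.26 and -0.74, and the first of these ended the call (adjusted p = 0.0524).

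Antimicrobial and humoral immune effectors were the next list called (camera adjusted p = 0.00989), with a median of -0.82. Of the 28 genes on this list only 13 were measured, 9 of them above background. The antifungal peptide gene Drs fell by 1.38 (SE 0.283, adjusted p = 0.0456), a call that held in 5 of 15 other settings and ended without any single array and under the deposited and median-centred scalings. Adjusted over the list alone 4 members passed, the others being DptB (-0.96, SE 0.220), AttD (-1.02, SE 0.247) and pirk (-0.82, SE 0.247), a negative regulator of the Imd pathway. This list lost its call without mock replicate 2 (adjusted p = 0.17), without NELF-depleted replicate 1 (0.0569) or 2 (0.0593), and under hybridization-control scaling (0.0588). The NELF subunits themselves made up the last list called (adjusted p = 0.035), and all 3 passed adjusted over the list alone, TH1 with a higher value that became -0.02 under hybridization-control scaling. Both dsRNA targets are among these 3 members, so the lower call came with the treatment and is no finding beyond it. With the replicate number as a block it was lost (camera adjusted p = 0.083). That call ended without any single array, with adjusted p-values from 0.0569 without NELF-depleted replicate 1 and 0.0694 or 0.0732 without untreated replicate 2 or 1, through 0.0723 without NELF-depleted replicate 2 and 0.113 without mock replicate 2, to 0.21 without mock replicate 1; it was 0.0588 under hybridization-control scaling. Of 21 measured Toll and Imd pathway components, 2 fell: spz, which encodes the Toll ligand, by 0.69 (SE 0.0896) and GNBP3, a recognition protein gene, by 1.11 (SE 0.211). Adjusted over the list alone 5 passed, among them Tl (-0.67, SE 0.153) and dl (-0.41, SE 0.0967), and the list was not called (median 0.00172, mean -0.118, direction of the test lower, adjusted p = 0.68).

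Heat shock and chaperone genes had a median of 0.19 over 11 measured members, 9 of them with higher values, and the list missed the threshold (adjusted p = 0.0572), with a median of -0.14 under hybridization-control scaling; it was called with each array centred on its median (0.34, adjusted p = 0.0144) and with only genes above the 40th percentile (adjusted p = 0.0363) or the median level (adjusted p = 0.021). With an estimated correlation its adjusted p was 0.921. The list holds 23 genes, so with 11 measured it was tested only in part. Hsp26, a small heat shock protein gene, rose by 0.96 (SE 0.148) and Hsp68 by 0.63 (SE 0.117), both also past the threshold adjusted over the list alone, while DnaJ-1 had a value of 0.23 (SE 0.0912). Neither rise turned negative under another scaling, but Hsp68 lost its call as deposited, centred on medians and on hybridization controls, and Hsp26 lost its call as deposited.

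**Figure D3:**
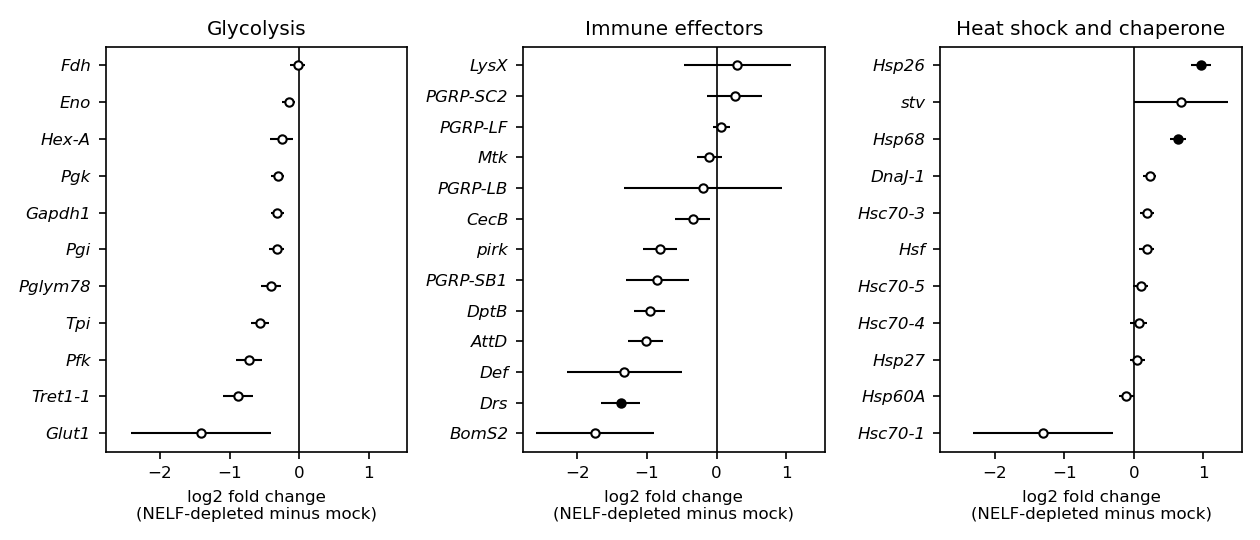
Log2 fold change (horizontal axis) of each measured member of 3 gene lists in NELF-depleted against mock cells; bars are 1 SE from limma, 2 arrays per group, and filled points passed the test over all genes. All 11 glycolysis values lie below 0, Drs is the filled point among immune effectors, and Hsp26 and Hsp68 are the filled points among heat shock genes.

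Signalling and cell identity lists were not called, but held single genes that changed. Of the other list members called over all genes, Hsp68 stayed called in 5 of the 15 other settings, GNBP3 in 6, E(spl)m3-HLH in 7, eater and ImpL2 in 8, Hsp26 in 10, Strica in 11, spz and br in 12, drpr in 13 and numb in 14. Among 23 hemocyte markers, the phagocytic receptor genes drpr (-0.87, SE 0.112) and eater (-0.87, SE 0.148) fell. Higher values of 0.42 and 0.52 in ush and Pxn passed only when adjusted over the list alone. In all, 6 members passed adjusted over the list alone, drpr and eater included (list camera adjusted p = 0.805). Of 22 ecdysone response genes, br, a transcription factor gene, fell by 0.97 (SE 0.129) and ImpL2, a secreted insulin-binding protein gene, by 0.60 (SE 0.110), and the same 2 passed adjusted over the list alone. Of 15 Notch and E(spl) genes, numb, which encodes a Notch inhibitor, fell by 1.08 (SE 0.124) and E(spl)m3-HLH by 0.83 (SE 0.157); 3 passed adjusted over the list alone, and the list median of -0.46 gave an adjusted p of 0.205. The caspase gene Strica fell by 0.75 (SE 0.101), the only 1 of 14 apoptosis genes to do so, while the TNF gene egr (-0.49, SE 0.103) passed adjusted over the list alone, as did 2 in all. None of 23 EGFR and receptor tyrosine kinase genes passed over all genes; Pvr (0.58, SE 0.122) and InR (0.68, SE 0.165), both receptor genes, were the 2 that passed adjusted over the list alone.

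Detoxification and oxidative stress genes went both ways (25 measured, median 0.0495, mean -0.0718, direction of the test lower, adjusted p = 0.805, none past the threshold over all genes and 9 adjusted over the list alone). The cytochrome P450 gene Cyp6a2 was at least 1.64-fold lower, the glutathione transferase gene GstE3 had a value of -0.51 (SE 0.124) and Men, which encodes malic enzyme, one of 0.45 (SE 0.101). None of the other 13 lists had a member past the threshold over all genes or adjusted over the list alone, and none was called. Elongation and pausing factors (20 measured) had a median of 0.0456, with Ssrp at 0.32 and Trl, the GAGA factor gene, at -0.32; RNA polymerase II and general factors (20 measured) had one of 0.0153, with hay at 0.31 and Polr2H at -0.17. Medians were 0.00157 for the 15 RNA interference genes (drosha 0.23, spn-E -0.27) and -0.0357 for the 12 JNK and JAK-STAT genes (msn -0.28, dome -0.29). Ribosomal protein genes (41 measured) had a median of -0.00716, with RpS19b at -0.67, and proteasome genes (24) one of 0.037, with Rpn2 at 0.17 and Prosbeta2 at -0.11. The 18 oxidative phosphorylation genes had a median of -0.0851, with ATPsyndelta at -0.27 and ox at -0.23. For DNA replication (23 measured) it was 0.0177, with Sld5 at 0.30 and Orc4 at -0.25, and for mitosis (19) 0.000606, with fzr at -0.47 and Bub3 at 0.15. Histone genes and their mRNA processing factors (8) gave -0.0664, with Slbp at 0.15 and mxc at -0.20. Actin cytoskeleton and adhesion genes (18) gave -0.05, with sdt at -0.66, and lipid and sterol genes (20) -0.0333, with mdy at 0.44 and Npc1a at 0.33. Markers of neurons, muscle, fat body, gut and germline had 12 measured members, only 4 of them above background (median -0.0203); bam was at least 1.4-fold lower by its group means, not past the test (adjusted p = 0.704).

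Against untreated cells, the same direction prevailed. NELF-B and Nelf-E had log2 fold changes of -2.0 (SE 0.170) and -2.45 (SE 0.155), and TH1 one of 0.16 (SE 0.127), not past the test. Limma with the intensity-dependent prior called 169 genes, 141 lower and 28 higher, among them QC at -2.37 (SE 0.0948, adjusted p = 1.7e-06). Nepl21, Spn77Ba, Cyp6a2 and CG7778 lay below background after depletion and were at least 5.07, 2.92, 1.84 and 1.81-fold lower; they stayed called in 12, 7, 6 and 7 of the 15 other settings, and each lost the call without untreated replicate 1 or 2 or NELF-depleted replicate 2. Bbg, CG9008, CG34328, Ip6k and CG2247 rose by 2.46, 1.63, 1.56, 1.42 and 1.09, and stayed called in 10, 9, 9, 14 and 13 of the 15 other settings. The single-prior test called 0 genes here too, with 1044 at an unadjusted p under 0.05; QC, Nelf-E, CG3505, CG14628 and Ir41a had its smallest p-values (adjusted p = 0.12), the last 2 with levels below background in both groups. All 28 genes named above moved the same way against untreated cells, and 24 passed the test. Gbs-70E, ckd, Ant2 and CG4250 were the 4 that did not, with adjusted p-values of 0.162, 0.0501, 0.0604 and 0.0508. Leaving out untreated replicate 1 or 2 or NELF-depleted replicate 1 or 2 left 66, 74, 86 or 77 calls. The lists called by camera were again NELF subunits (which hold both dsRNA targets), immune effectors (median -0.57) and glycolysis (median -0.24), 3 of 24. With an estimated correlation 0 were called (adjusted p = 0.707 each). The fry test called NELF subunits (adjusted p = 0.0193), Toll and Imd components (0.0428) and Notch and E(spl) genes (0.0401). It did not call glycolysis (0.195) or immune effectors (0.113).

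Calls against the 2 controls overlapped in 136 genes, 113 lower and 23 higher, with 0 genes in opposite directions. Independent lists of these sizes would share 1.53 lower and 0.0748 higher genes, and 100 simulated sets of unchanged arrays shared at most 0; those sets called 0 genes in either comparison, so they set no level for the overlap. Both comparisons use the same NELF-depleted arrays, and the count for independent lists leaves this out, so part of the overlap beyond it may come from them. The log2 fold changes of the 11981 genes correlated at r = 0.569 across genes, which are not independent replicates, against 0.501 in the simulation, and their covariance was 0.286 against 0.224. The simulated comparisons shared their NELF-depleted arrays in the same way, but held no link between arrays of the same replicate number. The single-prior test gave 0 shared calls.

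The contrast of NELF-depleted arrays with all 4 control arrays called 247 genes, 194 lower and 53 higher. QC (-2.41, SE 0.0821), CG34232 (-2.20, SE 0.162), Nelf-E (-2.43, SE 0.135) and NELF-B (-1.97, SE 0.147) were among the genes that fell, and Acsf2, an acyl-CoA synthetase family gene, was at least 2.78-fold lower, a call kept in 9 of 15 other settings. Nepl21 and Spn77Ba were at least 4.81 and 2.91-fold lower. Genes that rose included bbg (2.44), CG9008 (1.72), CG34328 (1.45), Ip6k (1.38) and CG2247 (1.09). TH1 had a value of 0.28 (SE 0.110, adjusted p = 0.34). The single-prior test called 0, with 1213 genes at an unadjusted p under 0.05 and the smallest p-values in QC, Nelf-E, Sgsh, Esyt2 and CG30178 (adjusted p = 0.111), the last below background in all groups. NELF subunits (which hold both dsRNA targets), immune effectors and glycolysis were called lower by camera (3 of 24 lists), and 0 with an estimated correlation (adjusted p = 0.544 each). The fry test called NELF subunits (adjusted p = 0.0129), Toll and Imd components (0.0415), ecdysone response genes (0.0329) and Notch and E(spl) genes (0.0329). Glycolysis and immune effectors were not called by it (0.081 each). Without NELF-depleted replicate 1 or 2 the gene count was 121 or 98, and without untreated replicate 1 or 2 it was 159 or 164.

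Mock against untreated cells, the effect of a dsRNA with no fly target, yielded no gene past the threshold. NELF-B, Nelf-E and TH1 differed by -0.06, -0.05 and -0.24. Limma called 0 genes with either prior, with 602 at an unadjusted p under 0.05 by the single-prior test and 408 by the intensity-dependent one, where 599.1 were due by chance. CG3505, CG14628, CG13810, CG31926 and CG3104 had the smallest p-values of the single-prior test (adjusted p = 0.19 each), and all of them but CG3505 lay below background in both groups. Across the 28 genes named above, the absolute log2 difference between mock and untreated cells had a median of 0.0886 and reached 0.402. No list was called (0 of 24, smallest adjusted p = 0.997).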

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

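All tests of explanations in this part except the first one on neighbouring genes were chosen only after the result was seen.

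Probe sets that carry no single gene name were left out of the comparisons, yet some gave more signal after NELF depletion than in the mock arrays. Of 5122 such probe sets, 10 were called higher and 12 lower in limma with the intensity-dependent prior over 18769 non-control probe sets. The highest were 1632298_s_at, which has no listed gene, at a log2 change of 2.11 (SE 0.128, adjusted p = 2e-05), and 1632841_x_at, which has 2 listed genes, at 1.84 (SE 0.224). Against untreated cells the same probe sets changed by 1.75 and 1.41. The strongest fall was in 1628884_at, without a listed gene, at -2.79 (SE 0.153).

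For the excess of falls over rises after NELF depletion, quantile normalization as the source is argued against by centring each array on its median, under which 88.9% of the calls were lower, as against 80.2% with it; the other scalings bear no weight here, since they shift the median of all genes down by themselves (by -0.0674 as deposited and -0.422 on hybridization controls). Dimmer NELF-depleted arrays were checked, for genes above background, by the fit with mock replicate 2 as the only mock array. Its spread was taken from the other groups, and 83.5% of its calls, all above background, were lower. This cannot decide the question, since mock replicate 2 was dim in its hybridization controls too. Their mean log2 level was 9.94 on it, against 10.6 and 10.4 on the NELF-depleted arrays. Over those genes this array was the dimmest, with a median log2 intensity of 8.09 against 8.36 and 8.13 on the NELF-depleted arrays. Its median over all probe sets was higher than theirs. Relative to hybridization controls its median gene lay at -1.86, near the other control arrays, and those of the NELF-depleted arrays at -2.24 and -2.25. A fall of the fly signal as a whole, by which the NELF-depleted arrays lay 0.382 below all control arrays relative to hybridization controls but overlapped with them relative to poly-A controls (-0.109), is argued against as the source of the excess, since 88.9% of calls were lower with the median centring, under which the median of all genes changed by 0.0624. Loss of NELF may be the source as a hypothesis, with dimmer NELF-depleted arrays left undecided and differences in scanning between arrays untested.

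The 247 genes called between NELF-depleted and all control arrays were weighed against a response to dsRNA of any sequence, which would move the same genes in mock cells. Their median ratio of the mock-minus-untreated change to the NELF-depleted change was 0.0382, which argues against that response as the source of the calls. A 95% bootstrap interval was 0.0108 to 0.0518. It came from resampling the 247 genes, which share the same arrays, so it leaves out the spread between arrays. Along the chromosomes 20 pairs of called genes were neighbours among the 6513 genes above background with a known place, against a mean of 8.87 and a central 90% range of 4 to 14 in a one-sided permutation test with 10000 draws matched on expression (p = 3e-04). The pairs include GstE2 with GstE3 and Idgf2 with Idgf3; 13 of the 20 moved the same way, where 13.3 were due from the shares of falls and rises alone. Without pairs that overlap or share a symbol stem 11 remained, against a central 90% range of 3 to 12 in the same permutation test (p = 0.12), so that a local effect on neighbouring genes cannot be told apart from overlapping transcripts or related sequences.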

How the results depend on the processing

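Alternatives to the intensity-dependent test other than that test itself, scaling on hybridization controls and the filters with the prior of all genes were chosen after the single-prior test had called no gene. For the single-prior test, limiting genes to those above the 40th percentile gave 37 calls against mock, 17 against untreated, 102 against both controls, 17 shared and both NELF targets (2); above the median it gave 175, 171, 270, 140 and 2; and the intensity-dependent prior gave 162, 169, 247, 136 and 2. All other alternatives left these at 0, and mock against untreated stayed at 0 throughout. The number of lists called, 3, became 0 with an estimated correlation, 5 with arrays centred on their medians (heat shock and ribosomal protein genes added) and 1 to 2 without single arrays, with glycolysis called each time. The filters raise the prior degrees of freedom from 1.2 to 1.94 and 3.99; adjusting over the same 7188 or 5990 genes with the prior of all genes gave 0 calls (smallest adjusted p = 0.15 and 0.125), so fewer tests alone did not give them. Replicates of genes below background differed by 0.787 to 0.863.

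For the intensity-dependent test, the counts against mock were 54 as deposited, 54 centred on medians, 2726 on hybridization controls, 74 with an offset of 50, 247 above the median level and 271 with the replicate block, and 68 to 126 without single arrays. Against untreated they were 2117 on hybridization controls, 89 with the offset, 270 with the block and 66 to 146 without single arrays; against both controls 143 centred on medians, 3350 on hybridization controls, 155 with the offset and 98 to 186 without single arrays. Shared calls were 53, 50, 1833, 71, 225 and 59 to 77 as deposited, centred, on hybridization controls, with the offset, with the block and without single arrays. The cause of these moves was not tested, except that leaving out an array leaves fewer samples. The replicate numbers are not taken to pair arrays, since the labels do not say what they mark. Deviations of same-numbered arrays correlated at -8.41e-05, 0.0116 and 0.0228 over all genes but at 0.145 to 0.158 above background. A shared effect on same-numbered arrays is thus not excluded. With the replicate block all 162 calls against mock were called again, the NELF subunit list lost its call (adjusted p = 0.083), and the single-prior test stayed at 0.

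None of the 162 genes changed sign in 15 alternatives to the intensity-dependent test (0 sign changes), with 1 gene not tested above the median level. This was close to given, since these genes were called for large changes on the same arrays. The smallest called rise was 0.426, and the largest shift of the median of all genes was -0.422. Of NELF-B, Nelf-E and the 28 genes named against mock, 8 kept the call in all 15: NELF-B, Nelf-E, Ip6k, QC, Esyt2, CG34232, Sgsh and CG34417. Values not past the test over all genes turned on hybridization controls, which shift the median of all genes by -0.42: TH1 to -0.0221 against mock, -0.25 against untreated and -0.13 against both, Ssrp to -0.0926, hay -0.11, DnaJ-1 -0.13, drosha -0.20, Rpn2 -0.20, Sld5 -0.13, Bub3 -0.25, Slbp -0.24 and Npc1a -0.0899. TH1 against untreated was also -0.26 as deposited and -0.0319 centred on medians, which shift the median of all genes there by -0.372 and -0.141, and Nelf-E in mock against untreated lay between -0.17 and 0.0638 without single arrays and was above 0 without untreated replicate 2 and, at 0.00273, without mock replicate 1. In the single-prior test, which called no gene, 1909 of 2079 further alternative values of single genes stayed on their side, 154 gained the call and 16 reversed as given here; of 383 for lists 362 stayed, 5 gained and 16 lost the call.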

Other observations

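The test on genes of the lysosome that did not prompt the list was set before its result was seen; the list itself and the gene families were chosen after the calls were seen.

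Some glutathione transferase and cytochrome P450 genes fell after NELF depletion against mock, although the detoxification and oxidative stress list fixed beforehand went both ways (25 measured, 13 higher and 12 lower, none called, median 0.0495, camera adjusted p = 0.805). Gene families were formed by the part of the symbol before its first digit. Gst symbols were merged by hand into 1 family, as were Cyp, PGRP and Ugt symbols, while ND- and ND-B stayed apart. Among 34 such families, glutathione transferases had 4 of 22 genes above background called lower, GstE2 (-1.59), GstO3 (-1.41), GstD3 (-1.08) and GstD9 (-0.62). GstT1 was the 1 called higher (0.52). By chance 0.438 falls were due (one-sided Fisher's exact test, adjusted p = 0.0282). That p-value is not independent support, since the merge was made after these falls were seen. Cytochrome P450 genes had 4 of 32 called lower, Cyp9c1, Cyp4d20, Cyp310a1 and Cyp12d1-d (adjusted p = 0.0595). No gene called in the intensity-dependent test changed sign under another scaling, which was close to given for genes called on large changes. Other genes that fell outside the fixed lists included the chitinase-like gene Idgf3 (-1.02), the amino acid transporter gene mnd (-1.25) and the chloride channel gene ClC-a (-1.21), and the ornithine decarboxylase antizyme gene Oda rose by 0.70; these were picked after their values were seen.

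Some genes of lysosomal proteins were among the falls. Besides Sgsh and LManII, Naglu (-1.13, SE 0.184), Ids (-0.93, SE 0.139), CREG (-1.33, SE 0.261), CtsB (-0.58, SE 0.0956) and Hexo2 (-0.52, SE 0.0959) fell; Sgsh, Naglu and Ids all encode enzymes of heparan sulfate breakdown. Over all 25 measured genes of a lysosomal list the camera p was 0.00179, and 0.0796 with an estimated correlation, but these 7 genes prompted the list. The 18 others gave a camera p of 0.91 and a median of -0.0493, which decides nothing, because all called genes had been taken out and 6 of the 18 had mock means below background. Whether lysosomal genes fell as a group stays open.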
